A study of Rattus norvegicus with 4 samples.

How the data were processed

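Gene expression was measured in the ventral prostate of male F344 rats, a laboratory strain, aged 6 weeks. One group received PhIP (2-amino-1-methyl-6-phenylimidazo[4,5-b]pyridine, a heterocyclic amine formed when meat is cooked) at 300 mg/kg and the other did not. Both were killed 2 days later. Each group held 4 rats, and RNA of 2 rats was mixed on each array, so each group has 2 arrays: control 1, control 2, PhIP 1 and PhIP 2. The unit of replication is therefore a pool of 2 rats, and the spread between pools is smaller than that between single animals would be. Biotin-labelled cRNA was made from 5 µg of total RNA and hybridised to a rat Affymetrix array with 31099 probe sets.

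The deposited values are MAS5 intensities (signals on a linear scale), one per probe set and array, per the submitters' processing notes, which name MAS5 without a version. The scaling target and the detection calls are not given in the sources used here. On each array, the mean signal after trimming 2% at each end was 100.0, and these means differed by at most 0.0013%, so the authors' scaling had put every array on the same trimmed mean. Signals over background were not used here, and the number of arrays limits the precision.

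Probe sets were named through the platform annotation: 20832 carried 1 gene symbol, 436 carried several and 9831 none. Of the single symbols, 20764 were matched by Entrez identifier to the RefSeq gene table of assembly GRCr8, and 0 changed. No gene was named from a probe set with several symbols. The 57 control probe sets of the manufacturer were left out, which left 31042.

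Signals were analysed as log2(signal + 10), the added constant being 10% of the trimmed mean. Fold changes are on that scale, which understates the change of dim genes. Probe sets whose mean log2 value over the 4 arrays lay above the 40th percentile were tested (18625, a mean signal plus constant of at least 24.3), and 12417 were not. The test was limma's moderated test (R 4.3.3, limma 3.58.1, lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment at 0.05, on 2 residual degrees of freedom and 5.67 prior ones. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

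Gene lists were compared with camera (limma, preset correlation 0.01) over 10507 genes, each represented by its single-gene probe set with the highest mean. Of 35 lists, 30 had at least 5 measured members and were tested, with Benjamini-Hochberg adjustment over these 30. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. Within each list, the limma p of its members was also adjusted over the list alone. The lists, the tests, the filter, the alternatives and the rule for naming genes were chosen before the data were examined, except for scaling to the hybridization controls, which was added later.

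The rule named, in each direction, the 12 genes with the largest log2 fold change among probe sets past the threshold with both PhIP arrays on the same side of both control arrays. Where fewer qualified, the places went to the lowest unadjusted p among genes with a log2 change of at least 1 and no overlap of the groups. It also named up to 4 members per list with the largest moderated statistic, and a fixed set that included Cyp1a1, Cyp1a2, Cyp1b1, Cdkn1a, Mdm2, Ccng1, Mki67, Pcna, Pbsn and Gpx2. Of 149 measured genes it took, those that the text needs are given. Of these 149, 33 had several tested probe sets, and in 5 the probe sets differed in sign.

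The steps were tested on simulated data for the comparison of PhIP with control: 18625 probe sets, of which 50 each were changed by 0.5, 1, 1.5 or 2 on the log2 scale. Of these, 0%, 18%, 26% and 72% were called, and 4 of 18425 unchanged probe sets were. Of 30 lists without a change, 0 were called. A cell cycle list shifted by 0.5 was found with camera (adjusted p = 1.93e-32) but not with an estimated correlation (adjusted p = 0.147). Genes were simulated as independent of each other, whereas the correlations estimated in the data ranged from −0.06 to 0.42 over the lists. The simulation therefore does not show how often camera calls unshifted lists whose genes vary together.

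Alternatives were other constants (none, 2% and 20% of the trimmed mean), no filter or one at the 60th percentile, quantile normalization, median centring, cyclic loess, scaling to the hybridization controls, eBayes without the trend or with robust estimation, the replicate number as a block, leaving out each array, other thresholds, and the mean of a gene's probe sets. Genomic spans were taken as gene lengths from the same GRCr8 table.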

Results

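The data were 4 arrays of rat ventral prostate, 2 from control rats and 2 from rats given PhIP at 300 mg/kg and killed after 2 days, each array a pool of 2 rats. The median signal was 25.5 and 27.4 on the control arrays and 23.2 and 23.1 on the PhIP arrays. Across tested probe sets, the log2 values of the PhIP arrays correlated at r = 0.987 and those of the control arrays at 0.972. Control 1 correlated with the PhIP arrays at 0.980 and 0.979, more closely than with control 2. Control 2 also had the highest ratio of 3′ to 5′ signal, a measure of RNA integrity, for actin (5.71 against 4.18, 3.93 and 3.49) and Gapdh (2.06 against 1.34, 1.45 and 1.44). The 18 probe sets for the hybridization controls, transcripts added in fixed amounts, were all lower in PhIP, on average by −0.23 on the log2 scale.

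The comparison of PhIP with control asks how gene expression in the ventral prostate differs 2 days after exposure. Stmn1, which encodes the microtubule-destabilising protein stathmin, rose from a signal of 373 ± 14.1 (SD, n = 2) in control to 873 ± 98.6 (n = 2) in PhIP, a log2 fold change of 1.20 ± 0.11 (SE; limma adjusted p = 0.0327). It was among 5 of 18625 tested probe sets past an adjusted p of 0.05, of which 4 rose and 1 fell. Of the other probe sets, 1384163_at (1.19 ± 0.10) and 1378608_at (2.11 ± 0.19) have no symbol in the annotation. The probe sets 1388850_at (1.30 ± 0.13) and 1388989_at (−0.91 ± 0.08) carry several. None of the 5 passed with no filter, quantile normalization, median centring or eBayes without trend, and Stmn1 did not pass after cyclic loess either. At an unadjusted p under 0.05 there were 2416 probe sets (13.0%), 998 higher and 1418 lower in PhIP. The groups did not overlap for 45.8% of probe sets, against 33.3% by chance. The higher share was 41.3% of those 2416, but 79.6% of the 3164 probe sets under that p after median centring and 89.1% of the 4136 after scaling to the hybridization controls. These scalings moved the median log2 fold change of all genes from −0.03 to 0.11 and 0.19. The number of calls was 2334 without control 1, 462 without control 2, and 0 without PhIP 1 or without PhIP 2, where Stmn1 had adjusted p = 0.219 and 0.566.

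The genes with the lowest p among those changed by at least 1 on the log2 scale did not pass the adjustment and are given as values. On the higher side, Cdkn1a, which encodes the cell cycle inhibitor p21 and is induced by p53, had a signal of 128 ± 15.1 in control and 407 ± 84.4 in PhIP (log2 fold change 1.59 ± 0.17, adjusted p = 0.0517). The transcription factor gene Mybl1 stood at 1.98 ± 0.26 (adjusted p = 0.0534). The mitotic genes Melk (1.25 ± 0.16) and Nusap1 (1.24 ± 0.17) and the replication genes Pclaf (1.20 ± 0.16), Uhrf1 (1.10 ± 0.15) and Pcna (1.00 ± 0.13) had the same adjusted p. So did the nuclease gene Aen (1.04 ± 0.14) and the repair methyltransferase gene Mgmt (1.05 ± 0.14). Ifi27l2b (1.11 ± 0.14, adjusted p = 0.0517) and Fundc1 (1.10 ± 0.14), a mitophagy receptor, completed the higher side. On the lower side, Wwox, an oxidoreductase gene at a fragile site, had a signal of 62.6 ± 0.21 in control and 11.4 ± 2.40 in PhIP (−1.77 ± 0.21, adjusted p = 0.0517). Fhit, a hydrolase gene that also lies at a fragile site, stood at −1.73 ± 0.33 (adjusted p = 0.110), and the receptor phosphatase gene Ptprm at −1.48 ± 0.20 (−0.72 ± 0.33 in another probe set). Psat1 (−1.25 ± 0.16) and Phgdh (−1.06 ± 0.17) encode enzymes of serine synthesis, Serpinh1 (−1.10 ± 0.13, and −0.62 ± 0.29 in another probe set) a collagen chaperone and Adamts5 (−1.17 ± 0.18, and −0.15 ± 0.22 in another probe set) a matrix protease. Tcerg1l (−1.11 ± 0.12), Sh2d4a (−1.13 ± 0.20), the muscle genes Acta1 (−1.03 ± 0.14) and Tnnc2 (−1.15 ± 0.18) and the alpha-globin gene Hba-a3 (−1.06 ± 0.21) were also lower.

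Gene lists were shifted in both directions: 16 of 30 passed camera's adjusted p of 0.05, 6 up and 10 down. None passed with an estimated correlation (lowest adjusted p = 0.221), and 7 of the 16 passed with fry. The estimated-correlation version, which rests on 2 residual degrees of freedom, cannot decide whether genes varying together made the calls. It also missed the simulated list of independent genes shifted by 0.5 (adjusted p = 0.147). Smooth muscle, fibroblast, ribosomal protein and DNA repair lists had estimated correlations of −0.040, −0.027, −0.021 and −0.018. Each still stood at adjusted p = 0.221. Cell cycle genes had the lowest camera p of all lists. Their median log2 fold change was 0.72 (SD over genes 0.35, 38 genes), a median fold of 1.65. Camera gave adjusted p = 8.46e-27, and adjusted p = 0.221 with an estimated correlation. When adjusted over the list alone, 28 of the 38 rose and 1 fell, and over all probe sets tested 0 passed. Those that rose included Pcna, the sliding clamp of DNA polymerase (626 ± 112 to 1259.5 ± 124), the kinetochore gene Spc25 (1.07 ± 0.15), the phosphatase gene Cdkn3 (1.06 ± 0.16) and the proliferation marker Mki67 (0.71 ± 0.13). The gene that fell was Ccnd1, which encodes the G1 cyclin D1 (−0.31 ± 0.10), named after its value was seen.

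Target genes of p53 were also shifted up, with a median of 0.24 (SD over genes 0.53, 22 genes). The adjusted p was 3.49e-05, and adjusted p = 0.221 with an estimated correlation. Of these 22, 7 rose and 1 fell adjusted over the list alone, with 4 that rose without PhIP 1 and 4 without PhIP 2. Besides Cdkn1a and Aen, Ccng1, which encodes cyclin G1, rose from 874 ± 64.1 to 1470.5 ± 11.9 (0.75 ± 0.09) and Sesn2, a stress-induced sestrin, by 0.89 ± 0.14. The member that fell was Bcl2l1, an inhibitor of apoptosis (−0.53 ± 0.17), of which another probe set stood at −0.012 ± 0.27. Mdm2, which encodes the ubiquitin ligase of p53, stood at 0.22 ± 0.13 (adjusted p = 0.516) in its brightest probe set. Its other tested probe sets stood at 0.84 ± 0.21 (adjusted p = 0.184) and 0.19 ± 0.21 (adjusted p = 0.718), with no overlap of the groups in any of the 3. DNA repair genes were shifted up by a smaller amount, with a median of 0.17 (SD over genes 0.30, 38 genes). Camera's adjusted p was 0.00162, and adjusted p = 0.221 with an estimated correlation. Of these, 2 rose adjusted over the list alone, Mgmt and Fen1, the flap endonuclease of replication and base excision repair (0.64 ± 0.14). Without control 1, 4 rose and 2 fell, and 0 rose without PhIP 1 or without PhIP 2.

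**Figure D1:**
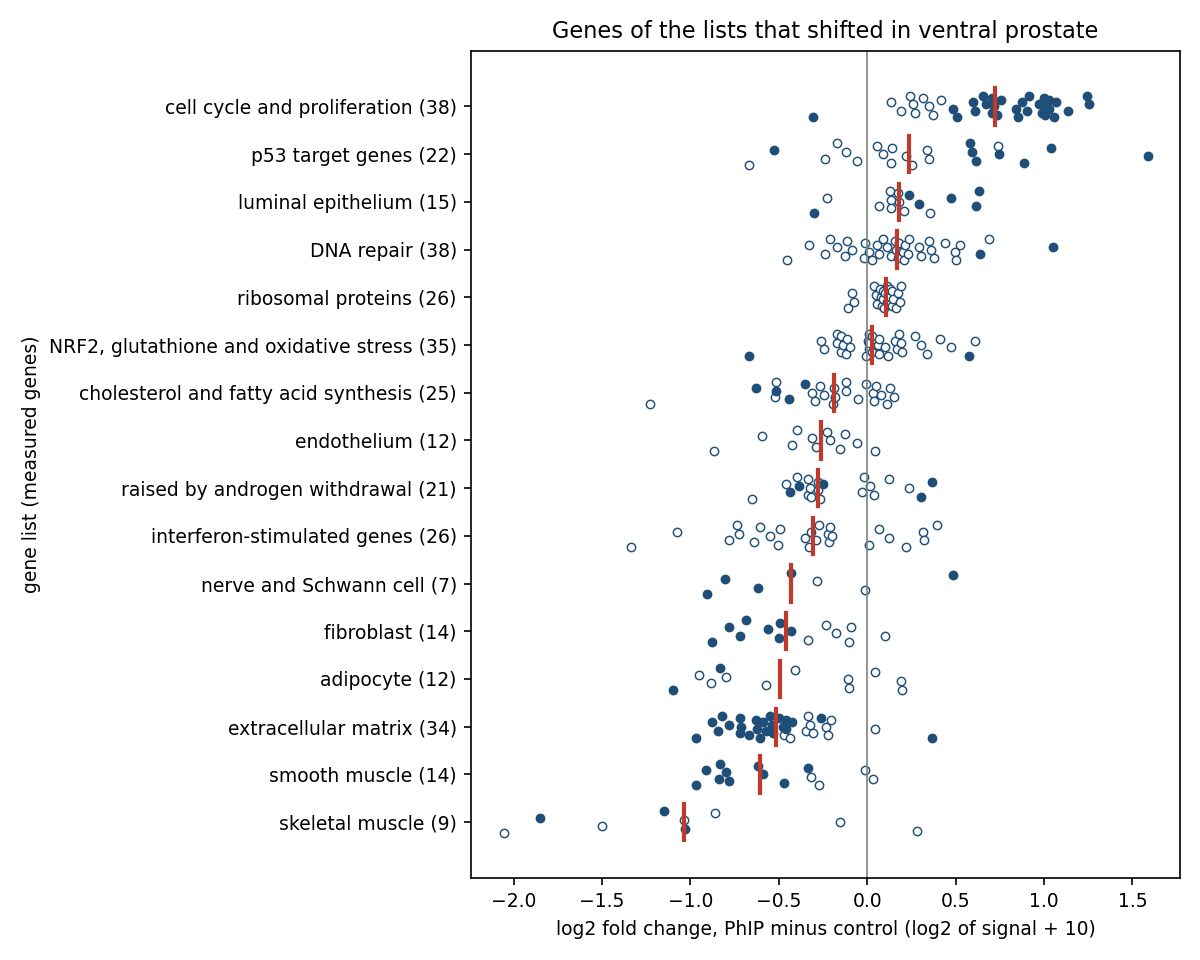
Log2 fold change (PhIP minus control, of signal + 10) on the horizontal axis for each measured gene of the 16 lists past camera's threshold, with 1 line per list, filled points for genes that passed adjusted over the list alone, open points for those that did not, and red bars for the medians. Medians run from −1.04 for skeletal muscle to 0.72 for cell cycle genes.

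Genes of the stroma were lower in PhIP. Smooth muscle genes had a median of −0.60 (SD over genes 0.33, 14 genes). The list had adjusted p = 3.33e-11, and adjusted p = 0.221 with an estimated correlation, and 10 of the 14 fell adjusted over the list alone. Among them were the smooth muscle actins Acta2 (1434.5 ± 170 to 795 ± 39.8, log2 fold change −0.84 ± 0.10) and Actg2 (−0.97 ± 0.12), the tropomyosin gene Tpm2 (−0.91 ± 0.13) and the myosin light chain gene Myl9 (−0.83 ± 0.12). Extracellular matrix genes had a median of −0.52 (SD over genes 0.27, 34 genes). Their adjusted p was 5.78e-16, and adjusted p = 0.221 with an estimated correlation, with 23 that fell and 1 that rose adjusted over the list alone. Without PhIP 1 the number that fell was 8 and without PhIP 2 it was 7. The collagen gene Col1a2 fell from 1951 ± 350 to 1048 ± 52.0 (−0.88 ± 0.12). The fibrillin gene Fbn1 (−0.85 ± 0.15), Col14a1 (−0.82 ± 0.14, and −0.32 ± 0.18 in another probe set) and Sparc, a collagen-binding glycoprotein (−0.53 ± 0.08), fell too. The gene that rose was Timp1, an inhibitor of matrix proteases (0.36 ± 0.09). Fibroblast genes, which share 3 collagens with that list, had a median of −0.46 (SD over genes 0.29, 14 genes). The adjusted p was 2.73e-07, and adjusted p = 0.221 with an estimated correlation. Of these, 8 fell adjusted over the list alone, among them the microfibril gene Mfap5 (−0.72 ± 0.11), Col1a1 (−0.78 ± 0.14) and Col3a1 (−0.50 ± 0.10), and 4 fell without PhIP 1.

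Luminal epithelial genes were shifted up, with a median of 0.18 (SD over genes 0.26, 15 genes). Camera gave adjusted p = 6.92e-05, and adjusted p = 0.221 with an estimated correlation, and 5 members rose and 1 fell adjusted over the list alone. The number that rose was 0 without PhIP 1 or without PhIP 2, 8 without control 2, 12 after median centring and 13 after scaling to the hybridization controls. The keratin gene Krt19 rose from 296 ± 35.3 to 464 ± 18.0 (0.63 ± 0.12). On the log2 scale, the luminal transcription factor gene Foxa1 rose by 0.61 ± 0.18, the tight junction gene Ocln by 0.47 ± 0.12 and the E-cadherin gene Cdh1 by 0.29 ± 0.07. The claudin gene Cldn4 fell (−0.30 ± 0.10) and was named after its value was seen. Ribosomal protein genes were shifted up by a median of 0.11 (SD over genes 0.08, 26 genes). Their adjusted p was 6.92e-05, and adjusted p = 0.221 with an estimated correlation. Of the 26, 0 passed adjusted over the list alone, but 8 rose and 1 fell without control 1 and 2 rose without control 2. After median centring 21 rose and after scaling to the hybridization controls 23 did. The list's call was lost after cyclic loess normalization.

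The secretory programme of the lobe gave no detectable shift. The 24 measured androgen-regulated and secretory genes had a median of −0.02 (SD over genes 0.22) and a mean of 0.03, with camera's direction up (adjusted p = 0.382), and a median of 0.20 after scaling to the hybridization controls. Probasin, the androgen-regulated secretory protein encoded by Pbsn, had a signal of 4648 ± 353 in control and 4458 ± 262 in PhIP (−0.06 ± 0.08, adjusted p = 0.759), with the opposite sign after median centring (0.08). The spermine-binding protein gene Sbp stood at 0.25 ± 0.07 (adjusted p = 0.206). With it, Slc45a3 (0.30 ± 0.08), Andpro (0.17 ± 0.05) and Creb3l4 (0.42 ± 0.14) had the largest moderated statistics, all higher in PhIP with no overlap of the groups. At an unadjusted limma p under 0.05, 6 of the 24 were higher and 2 lower. Of all 24, 11 were higher and 13 lower, and 0 passed adjusted over the list alone. Genes that rise when androgen is withdrawn were shifted down, with a median of −0.28 (SD over genes 0.27, 21 genes). The adjusted p was 0.0425, and adjusted p = 0.395 with an estimated correlation, and the call was lost without control 1, without control 2 (median −0.15) and without PhIP 1 (median −0.15). It was also lost after scaling to the hybridization controls (median −0.06), with eBayes without trend and with the mean of probe sets. The growth factor-binding genes Igfbp5 (−0.44 ± 0.10, and −0.84 ± 0.16, −0.43 ± 0.27 and −0.068 ± 0.38 in other probe sets) and Igfbp2 (−0.39 ± 0.10) and the matrix Gla protein gene Mgp (−0.25 ± 0.07) fell adjusted over the list alone. Timp1 and Gstm1, a glutathione transferase gene (0.30 ± 0.09) named after its value was seen, rose. Without control 1, 8 fell, and without PhIP 1 or without PhIP 2, 0 fell and 0 rose.

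**Figure D2:**
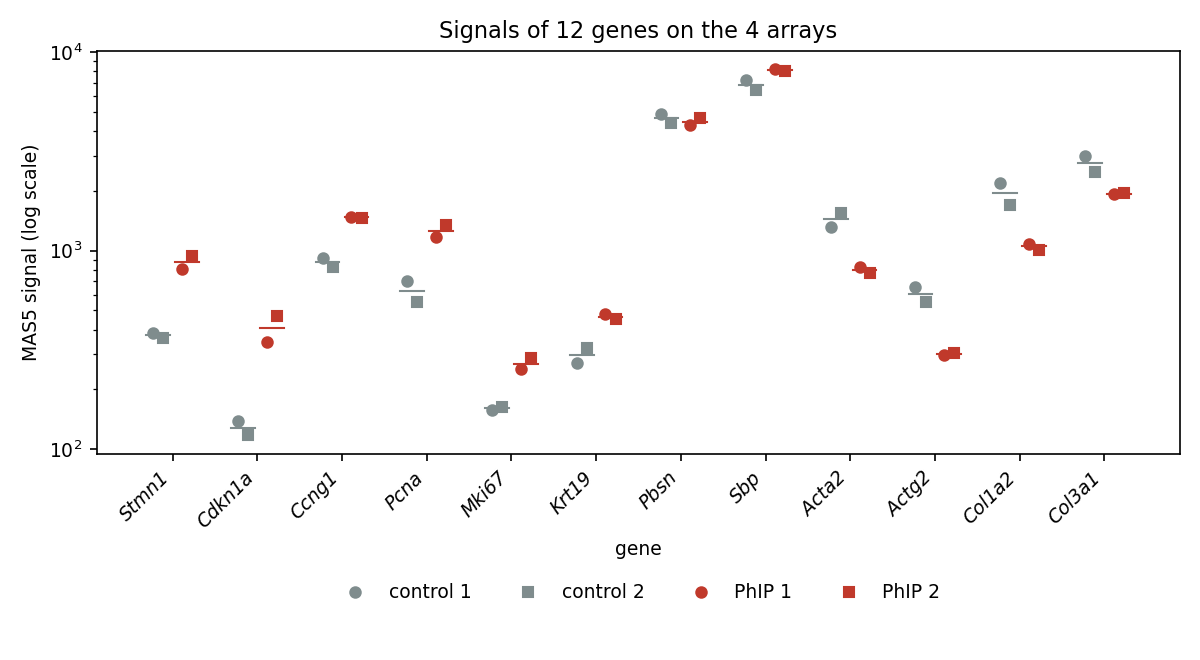
MAS5 signal on a logarithmic vertical axis for 12 genes along the horizontal axis, with 1 point per array (control in grey, PhIP in red, circles for pool 1 and squares for pool 2) and a line at each group mean. Stmn1, Cdkn1a, Ccng1, Pcna, Mki67, Krt19 and, by less, Sbp lie higher in both PhIP pools, the 4 muscle and collagen genes lie lower, and the Pbsn signals overlap.

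Lists for skeletal muscle, adipocytes, endothelium, nerve and red blood cells were lower in PhIP by their medians. Skeletal muscle and adipocyte genes also differed between pools of the same group. Skeletal muscle genes had a median of −1.04 (SD over genes 0.75, 9 genes), which was −0.20 without control 2 and −1.87 without control 1. The adjusted p was 0.000209, and adjusted p = 0.393 with an estimated correlation. The fast troponin gene Tnni2 had signals of 20.2 and 71.4 in control and 2.9 and 4.6 in PhIP. The light chain gene Myl1, chosen after its values were seen, had 5.2 and 306 in control and 4.5 and 9.1 in PhIP. Of the 9 genes, Acta1, Tnnc2 and Tnni2 fell adjusted over the list alone, and 7 genes fell without control 1. Adipocyte genes had a median of −0.49 (SD over genes 0.47, 12 genes). Camera gave adjusted p = 0.0387, and adjusted p = 0.523 with an estimated correlation, and the call was lost without control 1 and without PhIP 1 (median −0.23). Other losses came with no filter, the filter at the 60th percentile, quantile normalization, cyclic loess and eBayes without trend. Of these genes, the fatty acid-binding gene Fabp4 (−0.83 ± 0.21) and the lipase gene Lpl (−1.10 ± 0.28) fell adjusted over the list alone. The number that fell was 5 without control 2 or without PhIP 2, and 0 without control 1 or without PhIP 1. Endothelial genes had a median of −0.26 (SD over genes 0.25, 12 genes), which was −0.12 after median centring and −0.07 after scaling to the hybridization controls. Their adjusted p was 0.0137, and adjusted p = 0.393 with an estimated correlation, and this call too was lost without control 1 and after cyclic loess. None of the 12 passed adjusted over the list alone, with the receptor genes Tie1 at −0.86 ± 0.27 and Eng at −0.60 ± 0.18. Nerve genes had a median of −0.43 (SD over genes 0.48, 7 genes). The adjusted p was 0.0448, and adjusted p = 0.488 with an estimated correlation, and the call was lost without control 1, without control 2 and without PhIP 2. Quantile normalization, cyclic loess and the replicate block (adjusted p = 0.0734) ended it as well. Gap43 (−0.91 ± 0.26), Prph (−0.81 ± 0.22), S100b (−0.62 ± 0.21) and Pmp22 (−0.43 ± 0.11) fell adjusted over the list alone, with 2 that fell without control 2, 1 without PhIP 1 and 0 without PhIP 2. The myelin gene Mbp rose (0.49 ± 0.19) in its brightest probe set and was named after its value was seen, while others stood at 0.39 ± 0.22 and −0.15 ± 0.19. Without control 2, without PhIP 1 and without PhIP 2, 0 members rose. Of the genes on the red blood cell list, only the haemoglobin gene Hbb (2001 ± 522 to 1046 ± 303) and Alas2, the first enzyme of erythroid haem synthesis (−1.02 ± 0.27), were measured, too few for a list test. Both fell adjusted over the list alone. Hba-a3, given above, was not on that list.

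Among metabolic and immune lists, cholesterol and fatty acid synthesis was shifted down, with a median of −0.19 (SD over genes 0.31, 25 genes), which was 0.04 after scaling to the hybridization controls. The adjusted p was 0.00211, and adjusted p = 0.412 with an estimated correlation. Members that fell adjusted over the list alone, 4 in all, were the sterol synthesis genes Fdps (−0.63 ± 0.08), Cyp51 (−0.35 ± 0.07, and −0.60 ± 0.09 in another probe set) and Idi1 (−0.44 ± 0.11) and Srebf2, which encodes their transcriptional activator (−0.52 ± 0.13). The number that fell was 16 without control 2 (median −0.34) and 1 without PhIP 1 or without PhIP 2. The list's call was lost without control 1 (median −0.03, adjusted p = 0.398). Interferon-stimulated genes had a median of −0.31 (SD over genes 0.43, 26 genes). It was −0.18 after quantile normalization or cyclic loess, −0.17 after median centring and −0.13 after scaling to the hybridization controls. Camera gave adjusted p = 0.00324, and adjusted p = 0.393 with an estimated correlation, and 0 of the 26 passed adjusted over the list alone. This 0 depends on the setting: 8 fell with no constant, 7 with robust eBayes, 4 with eBayes without trend, 4 without control 1 and 1 without control 2. The antiviral genes Bst2 and Rtp4 stood at −0.78 ± 0.18 and −1.08 ± 0.29 and the regulator Irf7 at −0.61 ± 0.18. The median was −0.46 without control 2 and −0.19 without control 1, where the call was lost (adjusted p = 0.398), as it was with the filter at the 60th percentile. NRF2 and glutathione genes had a median of 0.03 (SD over genes 0.25, 35 genes), which was 0.16 after median centring and 0.24 after scaling to the hybridization controls. Their adjusted p was 0.0432, and adjusted p = 0.391 with an estimated correlation, and the call was lost without control 2, without PhIP 2, after quantile normalization or cyclic loess, and with eBayes without trend. Nfe2l2, which encodes NRF2 itself, rose (0.58 ± 0.10) and the metallothionein gene Mt2A fell (−0.67 ± 0.13) adjusted over the list alone. Without control 1, where the median was 0.13, 8 rose and 3 fell. Without control 2, 5 rose, and without PhIP 1 or without PhIP 2, 0 rose and 0 fell.

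Genes of the aryl hydrocarbon receptor response and of PhIP activation gave no detectable shift (median 0.0047 and mean −0.03, SD over genes 0.25, 8 genes; adjusted p = 0.963). The median was 0.14 after median centring and 0.21 after scaling to the hybridization controls. Of the 8 genes, 4 were higher and 4 lower. Arnt, the member with the largest moderated statistic, stood at 0.42 ± 0.24 (limma adjusted p = 0.492). Cyp1b1, a P450 of that response, stood at −0.31 ± 0.27 (adjusted p = 0.646) and Nqo1 at −0.26 ± 0.26 (adjusted p = 0.684). The glutathione peroxidase gene Gpx2, which was on the NRF2 list and not on this one, stood at −0.25 ± 0.24 (adjusted p = 0.680). The P450 genes Cyp1a1 (signals of 0.8, 1.5, 2.5 and 0.7 on control 1, control 2, PhIP 1 and PhIP 2) and Cyp1a2 (2.0, 2.4, 1.5 and 17.7) lay below the filter. The lists for oxidative phosphorylation (adjusted p = 0.0994), inflammation (0.103), immediate early genes (0.114), basal epithelium (0.169), MHC class II (0.249), oestrogen response (0.382), glucocorticoid response (0.439) and the circadian clock (0.474) did not pass. Neither did those for lymphocytes (0.745), apoptosis (0.780), macrophages (0.937) or the unfolded protein response (0.950). Some of these lists passed under other settings. With all 4 arrays, oxidative phosphorylation and inflammation did so after median centring and after scaling to the hybridization controls, and basal epithelium with the filter at the 60th percentile. With an array left out, immediate early genes passed without control 1, MHC class II without PhIP 1 and oxidative phosphorylation without PhIP 2. For the glucocorticoid list the median was 0.08 and the mean −0.02, and for the circadian list the test's direction was up with a median of −0.0015. Mast cells, neutrophils, urothelium and the other prostate lobes had fewer than 5 measured genes, with medians of −0.03 (4 genes), none (0 genes), −0.20 (1 gene) and −0.11 (4 genes).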

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

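Scaling to the hybridization controls was chosen after seeing the data, and all other settings before. Of 18625 probe sets, 5 passed (4 higher, 1 lower). The count stayed at 5 with no constant or one of 2%, and became 22 (11 higher, 11 lower) with 20%, 44 (26, 18) with the filter at the 60th percentile, 52 (31, 21) with robust eBayes, 164 (154, 10) after scaling to the hybridization controls, 3 (2, 1) after cyclic loess, 143 (77, 66) at adjusted p under 0.10 and 28 (16, 12) for a 2-fold difference in all 4 array pairs. It was 0 (0 higher, 0 lower) with no filter, quantile normalization, median centring or eBayes without trend, where limma left 3004, 2213, 3164 and 2248 probe sets at an unadjusted p under 0.05; the cause was not tested. Leaving out 1 array gave 0 to 2334 calls (0 to 1350 higher, 0 to 984 lower), with the lone array of a group assumed to vary like the other group; the low end came without PhIP 1 (1097 unadjusted) and without PhIP 2 (1046). Stmn1 lost its call in 7 of 17 alternatives, with log2 fold changes of 1.08 to 1.43 and adjusted p of 3.91e-05 to 0.566 over all 17.

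With the replicate number as a replicate block the count was 35 (20 higher, 15 lower). Arrays with the same number did not deviate together from their group means (correlation −0.056), which gives no sign of a shared batch but does not exclude one.

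Of 30 lists, 16 passed (6 up, 10 down), 11 to 18 under other constants, filters, normalizations, variance models and means of probe sets and 15 with the replicate block. With an estimated correlation, which also missed the simulated shift, 0 passed (0 up, 0 down) and with fry 7 (3 down). Leaving out 1 array gave 11 to 15 lists, 4 to 9 of them down. The cell cycle, extracellular matrix, smooth muscle, fibroblast, p53, luminal, DNA repair and skeletal muscle lists lost their call under no alternative that tested them other than the estimated correlation and, for cell cycle, extracellular matrix and skeletal muscle, fry. With the filter at the 60th percentile, skeletal muscle had 3 measured genes and was not tested. Its shift rested largely on control 2: the median was −1.04 with all arrays and −0.20 without control 2, where 4 genes were higher and 5 lower.

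Medians of lists followed the scaling. After scaling to the hybridization controls they were 0.44 for p53 targets, 0.38 for DNA repair, 0.34 for ribosomal protein, 0.41 for luminal, −0.29 for matrix, −0.38 for smooth muscle, −0.23 for fibroblast and −0.20 for nerve genes. The ribosomal protein median, 0.11 at first, moved the other way to 0.05 after quantile normalization or cyclic loess. Counts of list members moved with the setting too. After scaling to the hybridization controls, 5 matrix genes (23 before), 3 fibroblast genes (8), 0 cholesterol genes (4), 0 nerve genes (4) and 0 androgen-withdrawal genes (3) fell. Under that scaling, 11 p53 targets (7), 6 DNA repair genes (2), 13 luminal genes (5), 23 ribosomal protein genes (0) and 10 NRF2 genes (1) rose. After median centring, 14 matrix genes, 1 cholesterol gene and 0 androgen-withdrawal genes fell, and 12 luminal, 21 ribosomal protein, 4 DNA repair and 5 NRF2 genes rose. With eBayes without trend, 0 luminal and 0 NRF2 genes rose and 0 cholesterol, 0 adipocyte and 0 androgen-withdrawal genes fell. Interferon-stimulated genes that fell were 0 at first, 8 with no constant or one of 2%, 7 with 20% or robust eBayes, 5 with the filter at the 60th percentile and 4 with eBayes without trend.

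The test's direction turned only among lists and genes that had not passed. The median of the cholesterol list, which had passed, changed sign after scaling to the hybridization controls (0.044), while the test's direction stayed down. The aryl hydrocarbon list turned up with no filter or eBayes without trend (median 0.0047), quantile (0.034) and loess (0.041), and ranged from −0.11 to 0.075 without 1 array. The macrophage list turned up with no filter (median −0.081), the filter at the 60th percentile (−0.091), quantile (0.0086) and loess (0.036), and without 1 array ranged from −0.16 to −0.099. The unfolded protein list turned up with no filter (−0.0034), median centring (0.13), scaling to the hybridization controls (0.23) and the mean of probe sets (−0.00042), and ranged from −0.025 to 0.0097. Lymphocyte genes turned down with no filter (−0.052) and after scaling to the hybridization controls (0.24). Without 1 array, glucocorticoid genes ranged from 0.013 to 0.11, apoptosis genes from −0.069 to 0.021 and Pbsn from −0.14 to 0.018. Pbsn was 0.077 after median centring and 0.17 after scaling to the hybridization controls.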

Other observations

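The tests on cell cycle genes, on stromal genes and on the splits of the arrays were chosen after the result was seen. Those on genomic span were written after Wwox and Fhit had been seen but before any relation to span was computed, except that the intervals and the need for 20 genes over 100 kb were added after the values were known. Bootstrap intervals were drawn over genes, which are not independent replicates, and hold no spread between pools.

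Some genes moved within lists that did not shift. Among macrophage genes, Cd14, the co-receptor for bacterial lipopolysaccharide, rose by 0.50 ± 0.09 and the lysozyme gene Lyz2 by 0.29 ± 0.06 (SE, n = 2 and 2), both adjusted over the list alone, while the list as a whole had adjusted p = 0.937 with camera. Asns, which encodes asparagine synthetase, fell within the unfolded protein response list from 873 ± 50.3 to 540 ± 16.5 (−0.68 ± 0.10; adjusted p = 0.0534 over all probe sets tested with limma). The MHC class II gene RT1-Db1 (−0.79 ± 0.18, and −0.28 ± 0.19 in another probe set), the chemokine gene Ccl20 (−0.81 ± 0.17) and the growth factor gene Igf1 (−0.67 ± 0.18) also fell adjusted over their lists alone, and the prolactin receptor gene Prlr rose by 0.19 ± 0.05 in its brightest probe set and stood at 0.63 ± 0.10 and 0.88 ± 0.40 in others.

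Cell cycle genes were higher in both PhIP pools than in both control pools on average, with a median of 0.72. Without control 2, the pool with other RNA quality and skeletal muscle transcripts, the median was 0.74 (95% bootstrap interval over genes 0.53 to 0.82), which argues against that pool as the source. A larger epithelial share would raise luminal genes as much, but the cell cycle median exceeded the luminal one by 0.55 (two-sided permutation over genes, p = 3e-04; 38 and 15 genes, which are not independent replicates). Over 5 scalings the lowest median was that of the main one, 0.72 (0.61 to 0.90), and the others gave 0.74 to 0.94. None of them thus lowered it. They moved the median of all genes only between −0.03 and 0.19, too little to cancel 0.72, so they could not have decided otherwise. That the 4 arrays fell into these groups by chance stays open, as does the untested hypothesis that more cells of the lobe were cycling, or replicating DNA for repair, which counts of dividing cells, not analysed here, could decide.

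Smooth muscle, fibroblast and matrix genes were lower in PhIP, with a median of −0.49 over 59 genes. Without control 2 it was −0.58 (95% bootstrap interval over genes −0.66 to −0.47), which argues against that pool as the source, with control 1 as the only control. The highest median over 5 scalings was −0.27 (−0.36 to −0.21), so the sign held while the size depended on the scaling. These scalings moved the median of all genes only between −0.03 and 0.19, too little to cancel −0.49, so they could not have excluded scaling. An equal loss of every stromal cell type, as a smaller stromal part in the dissected tissue might give, stays open: endothelial and nerve genes lay 0.20 above smooth muscle and fibroblast genes, a difference that did not pass (two-sided permutation over genes, p = 0.138, 19 against 28 genes). A lower stromal share and lower expression in stromal cells cannot be told apart here.

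Genes with a long genomic span were lower in PhIP: the 235 genes over 300 kb had a median of −0.36 and 82.6% were lower, against −0.11 for 1151 genes of 100 to 300 kb and 0.0015 for 2635 genes under 10 kb. Across 10499 of 10507 genes (99.9% with a span in GRCr8), Spearman's rho between span and log2 fold change was −0.119 (p = 1e-04, the smallest that 10000 permutations of genes, which are not independent replicates, can give), against −0.068 and −0.038 in the other 2 splits of the arrays, and a drop in transcription that grows with span, as adducts that block the polymerase may give, is a candidate explanation that counts of nascent transcripts along long genes, not analysed here, could decide. Control 2 is argued against (rho −0.158 without it, 95% bootstrap interval −0.179 to −0.138), but without control 1 rho was −0.069, while the median over 300 kb was −0.37. Among the 5249 brighter genes rho was −0.107 (−0.133 to −0.081), so the relation was seen there too. That rho met the value written beforehand against dim probe sets. Its interval was held to a looser limit than that of control 2 and would have missed the stricter one, so dim probe sets stay open. Stromal genes with long spans stay open: rho was 0.029 among 230 genes of intracellular lists (permutation p = 0.651), the value written beforehand for that explanation, but only 14 of these exceed 100 kb, too few to decide, and without the 59 listed stromal genes rho was −0.118 (−0.116 without cell cycle genes too), which argues against those genes but not against stromal genes outside the lists. Of the 235 genes, 1 is on a smooth muscle, fibroblast, matrix, endothelial or nerve list. Of the same 235, 9 lie below the lowest of 28 smooth muscle or fibroblast genes (−0.97), with Wwox (931 kb), Fhit (1508 kb) and Ptprm (705 kb) among them. A set of 235 genes can reach lower than a set of 28 by its size alone, so this count does not bear on stromal genes.

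Splitting the 4 arrays into pairs in the 3 possible ways gave as many probe sets past adjusted p of 0.05 in 1 of 3 splits, the real one, with 5, and the highest other had 0. With 3 splits, no share under 0.05 can be reached.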
